A study of Homo sapiens with 3 samples.

How the data were processed

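Guide RNA abundance was measured in 3 libraries of genomic DNA from BT549 cells, an established line of triple-negative breast cancer. Per the labels' protocols, the cells stably expressed Cas9, were transduced at a low multiplicity of infection with a genome-wide lentiviral guide library, and were selected with puromycin. The selected pool was then divided. A portion was harvested directly (DMSO-Day0), and the others were grown for 7 days with the solvent DMSO (DMSO-Day7) or with 1 µM AZD6244 (AZD-Day7). AZD6244 is selumetinib, an inhibitor of the kinases MEK1 and MEK2. Guides were amplified from genomic DNA by nested rounds of PCR and sequenced, without molecular identifiers being described in the labels.

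The deposited table holds read counts, as whole numbers that were not normalized, for 119461 guides in the 3 libraries. MAGeCK 0.5.9.4 is named in the submitters' processing notes, without its role, and the trimming and matching of reads to guides are not given in the sources used here. Guide names carry an A or a B, as the sub-libraries of the human GeCKO library do. There were 63950 guides under A names and 55511 under B names. The table covered 18902 genes, of which 18167 had 6 guides, 1795 microRNA targets with 6834 guides, and 1000 non-targeting guides. All microRNA and non-targeting guides stood under A names. No guide sequences were used here, so positions and the number of matching genomic sites of a guide were not analysed. Gene names are those of the table. Of the 18902 names, 17372 were current symbols in a RefSeq gene table of assembly GRCh38.p14, 1350 were older symbols of a current gene, 70 were gene numbers found there, and 110 were not matched. Among names printed here, LOC100132247 is now NPIPB5 and WASH1 is WASHC1.

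Each group had 1 library. There was no replicate check, and the count models that need residual degrees of freedom could not be fitted. Every test below compares these libraries, not the conditions. Counts were scaled by the median of ratios over the 3 libraries (size factors 0.389, 1.69 and 1.52 for DMSO-Day0, DMSO-Day7 and AZD-Day7). Guides with a mean scaled count of at least 30 over the 3 libraries were kept, which left 82429 guides, 50102 of sub-library A and 32327 of sub-library B. Log2 fold changes were computed with a pseudocount of 1 on scaled counts. Guides were ranked after division by the spread, from the median absolute deviation times 1.4826, of guides of like abundance in 50 bins. For each target with at least 3 kept guides (18335 targets), ranks were combined by robust rank aggregation with alpha 0.1, in each direction. P-values came from 1000000 random draws of as many evenly distributed ranks as the target had kept guides, and were adjusted by the Benjamini-Hochberg method. These draws made no distinction between the sub-libraries. A target was called at an adjusted p under 0.1. Target values are the median log2 fold change over kept guides, with the SD over those guides. That SD describes guides, not replicates.

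The 27 gene lists comprised housekeeping complexes, signalling pathways around MEK and growth control, protein quality control, olfactory receptors as genes not used by these cells, and the microRNA targets. For each list the median of its members' values was set against 10000 random lists of the same size, matched on mean abundance in 10 bins. A list is said to lie below or above the random range when its median was outside the central 95% of them. That is a description of these libraries, not a p-value. List calls were also counted with p-values adjusted over the list alone. Ratios of single guides carry exact (Clopper-Pearson) 95% intervals, which cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

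The named targets were, per comparison, the 10 with the smallest p in each direction, up to 2 lowest and 2 highest members of each list, PSMG2 (named in the title of the series) with PSMG1, PSMG3, PSMG4 and POMP, and MAP2K1 and MAP2K2. The tests of the comparisons, the lists, this rule and the alternatives listed next were chosen before the data were examined. Added after seeing the data were a filter on the mean scaled count of at least 30 over the 2 libraries compared, called the pair filter below, the restriction of the growth ratio to sub-library A, and the tests that the closing parts name as chosen after a result was seen. Targets named only for sub-library A guides or for the pair filter were chosen after their values were seen.

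These alternatives were scaling by total counts or by non-targeting guides, pseudocounts of 5 and 10, no filter, a filter at 100, a filter on DMSO-Day0, ranking by plain log2 fold change, alpha of 0.05 and 0.25, a sum of scaled guide values in place of rank aggregation, leaving out the most extreme guide, each sub-library alone, a threshold of 0.05, means over guides, and a growth correction. Total-count scaling moved the median of all targets by 0.24 on the log2 scale in DMSO-Day7 and by 0.23 in AZD-Day7 against DMSO-Day0, and by 0 between the day 7 libraries. Scaling on non-targeting guides moved it by 0.21, by 0.15 and by -0.017. Between the day 7 libraries this median responds little to scaling, because guides with 0 counts in both stay at 0. It therefore does not show that values there are independent of scaling. The median of microRNA targets, all under A names, went there from 0.026 to -0.039 with non-targeting scaling.

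The procedure was tested on simulated counts with 50 targets planted at each of 4 changes. Against DMSO-Day0 with all guides, 0 of 50 planted 2-fold and 0 of 50 planted 4-fold depletions were called, in DMSO-Day7 and likewise in AZD-Day7, with 0 and 3 of 18135 unchanged targets called. For AZD-Day7 against DMSO-Day7 with all guides, 6 of 50 depletions at 2-fold and 27 of 50 at 4-fold were called, and 31 and 49 of 50 enrichments, with 5 of 18135 unchanged targets. With sub-library A alone (10196 targets), 9 and 39 of 50 planted depletions were called in DMSO-Day7 and 1 and 25 of 50 in AZD-Day7 against DMSO-Day0, with 8 and 10 of 9996 unchanged targets called in either direction. With the pair filter (14595 targets between the day 7 libraries), 18 and 45 of 50 planted depletions were called there, with 8 of 14395 unchanged targets. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.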

Results

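The screen asked which gene knockouts changed the growth of BT549 cells, a triple-negative breast cancer line, over 7 days in culture and under the MEK inhibitor AZD6244. Guide counts stood in for the number of cells carrying each knockout. There were 3 groups of 1 library each, namely the pool before treatment (DMSO-Day0), the pool after 7 days with DMSO (DMSO-Day7) and the pool after 7 days with 1 µM AZD6244 (AZD-Day7). Total counts were 40846787 in DMSO-Day0, 149760269 in DMSO-Day7 and 136143188 in AZD-Day7. Medians over the 119461 guides were 185, 197 and 164 counts. No group was replicated, so differences between libraries could not be set against the spread between replicates.

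The sub-libraries differed in how they came through the culture. The median count of sub-library A guides was 193 in DMSO-Day0, 831 in DMSO-Day7 and 747 in AZD-Day7, while that of sub-library B guides was 164, 1 and 0. Among guides against genes with at least 100 counts in DMSO-Day0, 15966 of 30118 in sub-library B had at most 5 counts in both day 7 libraries (53.0%, exact 95% interval 52.4 to 53.6%). In sub-library A these were 16 of 36954 guides (0.0433%, interval 0.0248 to 0.0703%). The loss in sub-library B had little to do with the gene targeted. It took 51.4% of guides against olfactory receptors, which these cells do not use (interval 47.3 to 55.4%), and 55.2% of guides against essential genes of ribosome, proteasome, spliceosome, RNA polymerases, DNA replication and the chaperonin TRiC (interval 49.9 to 60.4%). Among sub-library B guides over 30 counts in all 3 libraries, the rank correlation across guides was 0.980 between the day 7 libraries, 0.407 between DMSO-Day7 and DMSO-Day0, and 0.383 between AZD-Day7 and DMSO-Day0. In sub-library A these values were 0.937, 0.930 and 0.894. Guides are not independent replicates. Because of this loss, list medians and counts of called targets against DMSO-Day0 are given below for all guides and for sub-library A alone. Values of single targets are for all guides unless sub-library A is named.

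**Figure D1:**
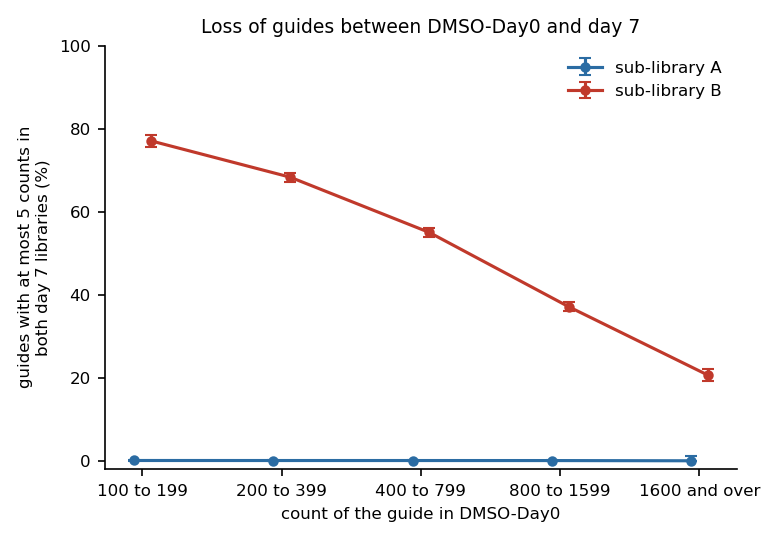
Percent of targeting guides with at most 5 counts in both day 7 libraries (vertical axis), by the count of the guide in DMSO-Day0 (horizontal axis), for sub-library A (blue) and sub-library B (red), with exact 95% intervals of counting error. The share lost in sub-library B ran from 77.05% in the lowest step to 20.6% in the highest, and in sub-library A it stayed below 0.1% in every step.

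Non-targeting guides give a background for each comparison, although some of them were lost at day 7, as described further below. Over 906 kept non-targeting guides, the SD of log2 fold changes was 2.86 in DMSO-Day7 and 2.87 in AZD-Day7 against DMSO-Day0, where counting error alone would give 0.427 and 0.421. Between AZD-Day7 and DMSO-Day7 it was 0.576, against 0.585 from counting error. Among the 812 non-targeting guides over 30 scaled counts in all 3 libraries, the SDs were 1.16, 1.19 and 0.462, against 0.106, 0.107 and 0.0783 from counting error. Guides against olfactory receptors in sub-library A had SDs of 0.676, 0.730 and 0.518 in the same comparisons, against 0.144, 0.146 and 0.120. In sub-library B, 671 such guides had SDs of 4.79 in DMSO-Day7 and 4.85 in AZD-Day7 against DMSO-Day0, with medians of -7.40 and -7.58. Between the day 7 libraries their SD was 0.550.

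Over 7 days without drug, guides against genes of protein synthesis, protein breakdown and cell division had low medians among gene lists. With all guides, 59 of 62 cytosolic ribosomal protein genes had values below 0 (median log2 fold change -0.96, lower than all 10000 random lists, whose median was -0.33). Proteasome subunits had a median of -1.06 (percentile 0.200 among random lists), with 25 of 28 members below 0, and spliceosome components one of -1.29 (percentile 0.0100). Genes of mitosis and cohesin had a median of -1.60, lower than all random lists. Medians also lay below the random range for aminoacyl-tRNA synthetases, which charge tRNAs (-0.93), DNA replication (-0.75), translation initiation and elongation factors (-0.73), the mitochondrial ribosome (-0.56), RNA polymerases and general transcription factors (-0.54), and cell cycle kinases and G1/S regulators (-0.44). Olfactory receptors lay above the random range (-0.11, percentile 98.95). The median of microRNA targets, all of whose guides stood in sub-library A, was 0.06 and within the range of random lists from sub-library A (percentile 92.0). The median of all targets was -0.19, and under total-count and non-targeting scaling that of olfactory receptors turned positive, at 0.13 and 0.10. Lists below the random range numbered 10, against 2 with means over guides in place of medians and 0 with sub-library B alone.

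Sub-library A, which kept its guides, gave smaller values in the same direction for most of these lists under the main scaling. Signs of values this small depend on the scaling, as total-count scaling raised the median of all targets by 0.24. The median was -0.39 for 13 aminoacyl-tRNA synthetases, -0.34 for 15 proteasome subunits, -0.29 for 12 genes of mitosis and cohesin, -0.23 for 32 ribosomal proteins, -0.22 for 17 RNA polymerase and transcription factor genes, and -0.20 for 15 translation factors, all below the random range. The SWI/SNF, Mediator and SAGA complexes, which regulate transcription (-0.14), and the ubiquitin system with p97 (-0.13) also lay below it. DNA replication (-0.15) and the spliceosome (-0.13) lay within the range, and the mitochondrial ribosome changed sign, at 0.03. Above the range lay lysosomal hydrolases and membrane proteins (0.26), growth-suppressing regulators (0.25, 2 of 18 members below 0) and olfactory receptors (0.20). With all guides, growth-suppressing regulators lay within the range (-0.06, percentile 80.5, 22 of 35 members below 0).

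No target was called depleted or enriched in DMSO-Day7 against DMSO-Day0 by rank aggregation with all guides. At an unadjusted p under 0.05 there were 892 depleted and 858 enriched targets where 917 would arise by chance in each direction, and the sum method called 3 and 0. The lowest rank aggregation p-values for depletion belonged to AGAP4 (log2 fold change -3.16, SD over guides 3.46, 6 of 6 guides down), LOC100132247 (-0.94, SD 0.27, 5 of 5), SPDYE5 (-2.17, SD 0.89, 4 of 4) and WASH1 (-2.94, SD 3.33, 6 of 6). All of these belong to families with near-identical copies in the genome, so that their guides are uncertain as to which copy they act on. For enrichment, LYPD3 came first (-0.11, SD 6.09, with 2 of 5 guides up), and CLUL1 had a value of 1.70 (SD 1.15, 3 of 4 up). The rising CLUL1 guides were all of sub-library B, and its kept sub-library A guide stood at -0.16. With p adjusted over the list alone, RPL24 and RPS9 passed among ribosomal proteins, POLE2, RPA1 and RRM2 among DNA replication genes, POLR2D among RNA polymerases, MYC in the ERK pathway, and CCNE1 and CDK6 among cell cycle regulators. The insulin-like growth factor receptor IGF1R passed as enriched in its list (5.66-fold, 3 of 3 guides up), as did the kinase MAPK7 among reported modifiers of MEK or RAF inhibitor response (-0.28, SD 6.03), although only 2 of 5 MAPK7 guides were up and the highest went from 0 counts to 5. Neither passed over all targets.

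With sub-library A alone, 10 targets were called depleted and 0 enriched, with 385 and 468 at an unadjusted p under 0.05, where 510 would arise by chance in each direction. They included TBCC, a cofactor of tubulin folding (-3.33, SD 1.62 over 3 guides), POLR2D, a subunit of RNA polymerase II (-2.02, SD 0.75), the ribosomal protein gene RPL36A (-2.23, SD 2.10), and LOC100132247 (-1.05, SD 0.30) and SPDYE2 (-0.92, SD 0.29) of multicopy families. The rest were LOC100287399 and the microRNA targets hsa-mir-3687, hsa-mir-4754, hsa-mir-619 and hsa-mir-7641-1, whose number of matching genomic sites was not analysed. Simulated 4-fold depletions were called for 0 of 50 targets with all guides and for 39 of 50 with sub-library A alone, so the count of 0 with all guides does not show that depletion was absent. MAP2K1, which encodes MEK1, had a value of -0.55 (SD 1.79, 4 of 4 guides down), and MAP2K2, which encodes MEK2, one of -4.57 (SD 5.75), where 2 of its 4 kept guides had at most 5 counts in both day 7 libraries.

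**Figure D2:**
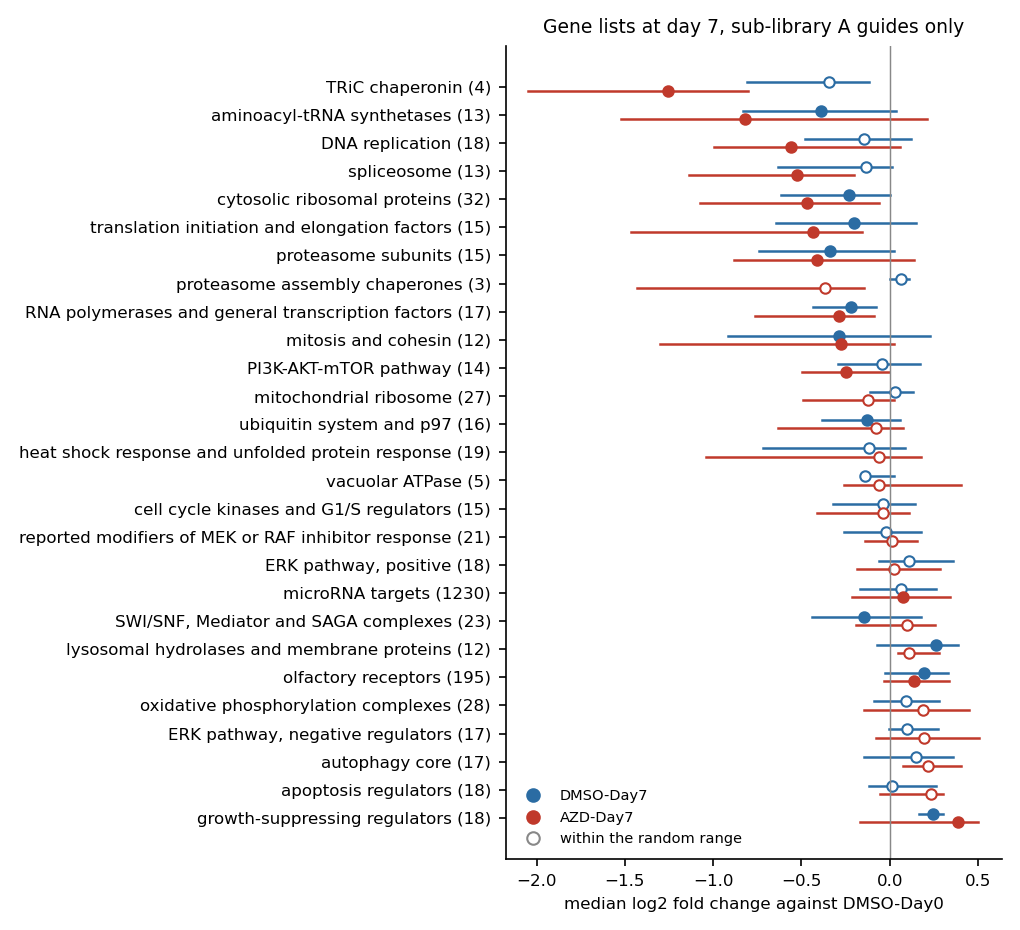
Median log2 fold change against DMSO-Day0 (horizontal axis) of each gene list (vertical axis, number of measured members in parentheses), from sub-library A guides alone, in DMSO-Day7 (blue) and AZD-Day7 (red). Lines span the interquartile range of members, filled points lie outside the central 95% of random lists and open points within it. TRiC (-0.35 and -1.26) and DNA replication (-0.15 and -0.56) lay lower in AZD-Day7 than in DMSO-Day7, and growth-suppressing regulators lay at 0.25 and 0.39.

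After 7 days with AZD6244, most of these housekeeping groups had lower medians than in DMSO-Day7, while that of cell cycle kinases and G1/S regulators was -0.35 and within the random range (percentile 14.9). With all guides, the median log2 fold change was -2.15 for the spliceosome, -1.55 for ribosomal proteins, -1.56 for DNA replication and -1.17 for the ubiquitin system and p97, each lower than all 10000 random lists. TRiC, which folds tubulin and actin, had a median of -4.01 over 7 members (percentile 2.39). Aminoacyl-tRNA synthetases (-1.67), mitosis and cohesin (-1.63), proteasome subunits (-1.35), RNA polymerases (-0.92), the mitochondrial ribosome (-0.79) and translation factors (-0.77) also lay below the random range. Proteasome assembly chaperones had a median of -1.74 over 9 genes (percentile 2.76). Above the range lay olfactory receptors (-0.09, and 0.15 and 0.06 under total-count and non-targeting scaling). The median of all targets was -0.24. Lists below the range numbered 11, against 5 with means over guides and 0 with sub-library B alone.

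In sub-library A alone, the median was -1.26 for 4 TRiC genes, -0.82 for aminoacyl-tRNA synthetases, -0.56 for DNA replication, -0.53 for the spliceosome, -0.47 for ribosomal proteins, -0.44 for translation factors and -0.41 for proteasome subunits, all below the random range. RNA polymerases (-0.28), mitosis and cohesin (-0.27) and the PI3K-AKT-mTOR pathway (-0.25) lay below it as well. Growth-suppressing regulators, such as tumour suppressors of the Hippo and TGF-beta pathways, had a median of 0.39 (percentile 99.9), with 5 of 18 members below 0, whereas with all guides it was -0.07 and within the range (percentile 83.1, 19 of 35 below 0). Their highest members were AMOTL2 (1.35), APC (0.80) and SMAD4 (0.77), and TGFBR1 was lowest (-0.76). Olfactory receptors (0.14, percentile 98.8) and microRNA targets (0.08, percentile 99.5) lay above the range of random lists from sub-library A too.

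In AZD-Day7 against DMSO-Day0, 9 targets were called depleted and 0 enriched by rank aggregation over all guides. Unadjusted there were 932 and 899, where 917 would arise by chance in each direction, and the sum method called 5 and 1. The transcription factor MYC fell, with a log2 fold change of -3.16 (SD 2.10) and 5 of 5 guides down. That value rests on 3 sub-library B guides, and with 2 kept sub-library A guides (-0.50 and -5.91, the latter from 23 counts to 0) MYC could not be tested in sub-library A. The sub-library B guides of MYC (-5.06, -3.03 and -3.16) lay above the median of sub-library B olfactory receptor guides (-7.58, SD 4.85). That median was not matched on starting count, and these MYC guides had 1953 to 3316 counts in DMSO-Day0. The share lost in sub-library B was 20.6% from 1600 counts upwards, against 77.05% in the lowest step. Whether the MYC guides fell beyond the loss of that sub-library therefore cannot be told. The same limit applies to sub-library B guides of the other called targets. POP5, a protein subunit of ribonucleases P and MRP, fell by 3.31 (SD 1.482, 6 of 6 guides down). ENPP7 fell, with a value of -1.85 (SD 2.34, 4 of 6 guides down), but stood at 0.34 in sub-library A. The other called targets were SPDYE5 (-3.70, SD 0.87), WASH1 (-4.57, SD 3.39), AGAP4 (-3.62, SD 3.19), PKD1 (-3.10, SD 1.94), BAGE2 (-2.61, SD 1.11) and GAGE1 (-1.09, SD 1.28), all from families or segments with near-identical copies and therefore uncertain. With p adjusted over the list alone, 11 ribosomal protein genes passed, among them RPL10A, RPL24, RPS23 and RPS9. The synthetase genes AARS, DARS, FARSA, FARSB and LARS passed likewise, as did CCT8 of TRiC, PSMG4 of the proteasome assembly chaperones, and UBE2M and USP7 of the ubiquitin system. As enriched, IGF1R passed (2.61, SD 0.71, 3 of 3 guides up), as did ETS2, MAPK7, OR8B2, and PRPF19 and PRPF31 of the spliceosome, but PRPF19 (-4.39), PRPF31 (-4.23), OR8B2 (-3.53) and MAPK7 (-0.49) had medians below 0.

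Sub-library A alone gave 19 depleted and 0 enriched targets, with 483 and 513 at an unadjusted p under 0.05. Of the 9 called with all guides, 5 could be tested there and 1, WASH1, was called again. Among the 19 were PSMG4 (-2.50, SD 1.93 over 3 guides), the mitochondrial protease gene LONP1 (-2.23, SD 0.68), POLR2D (-2.87, SD 1.62), SYMPK, a scaffold of mRNA 3' end processing (-2.86, SD 1.13), and RPLP2 (-1.82, SD 0.28). The target hsa-mir-6859-1, a microRNA with several identical copies, had the lowest value of these (-7.50, SD 2.56 over 4 guides). Also called were the microRNA targets hsa-mir-1233-1, hsa-mir-1299, hsa-mir-3135b, hsa-mir-3687, hsa-mir-663a and hsa-mir-7641-1. The rest were CDK11B, DUX2, FAM86B1, SNRNP25, and LOC100132247 and SPDYE2 of multicopy families. For CDK11B, DUX2, FAM86B1 and SNRNP25 the number of matching genomic sites was not analysed either, so their calls may be uncertain too. Plain log2 ranking in place of abundance-scaled ranking called 0 depleted targets with all guides, and simulated 4-fold depletions were called for 0 of 50 targets with all guides and 25 of 50 with sub-library A.

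Depletion of essential genes was compared between the day 7 libraries through their shared starting library. Pooled over 193 targets of the 6 essential lists, the median log2 fold change was -0.95 in DMSO-Day7 and -1.47 in AZD-Day7, a ratio of 1.55 (bootstrap 95% interval 1.28 to 2.03 over targets), and 143 of 193 targets were lower in AZD-Day7. In sub-library A the medians were -0.22 and -0.50, a ratio of 2.31 (interval 1.21 to 3.42), with 74 of 99 targets lower in AZD-Day7. That ratio holds for the main scaling only. Total-count scaling raised the median of all targets in DMSO-Day7 by 0.24, a shift that would carry the -0.22 across 0. The median difference between the libraries in sub-library A was -0.28 for ribosomal proteins (interval -0.49 to -0.13), -0.37 for the spliceosome (-0.62 to -0.04), -0.32 for DNA replication (-0.48 to -0.05), -0.14 for proteasome subunits (-0.46 to 0.30), -0.11 for RNA polymerases and transcription factors (-0.65 to 0.23) and -0.91 for 4 TRiC genes (-2.16 to -0.07). Across the 18335 targets the log2 fold changes of the day 7 libraries correlated at r = 0.969, where unchanged libraries sharing DMSO-Day0 gave 0.979 in simulation. In sub-library A r was 0.639 against a simulated 0.478, and the covariance was 0.124 against a simulated 0.0545. The control consisted of 1 library and could not be split, so part of the excess may come from it.

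Between AZD-Day7 and DMSO-Day7, which compares drug with solvent at equal time, 9 targets were called depleted and 0 enriched. At an unadjusted p under 0.05 rank aggregation gave 1060 depleted and 919 enriched targets, where 917 would arise by chance in each direction, and the sum method called 0 and 0. MYC, a downstream effector of MEK and ERK signalling, fell, with a log2 fold change of -1.28 (SD 2.03) and 5 of 5 guides down. Its counts went from 1515 to 302, from 2510 to 934 and from 2497 to 1452 in the guides of sub-library B. MYC stayed called in 9 of 17 alternative settings, and the growth correction, which left 0 called targets, brought its value to -0.59. By construction the correction raises values of guides that fell from DMSO-Day0 to DMSO-Day7, as the sub-library B guides of MYC did. The change to -0.59 therefore says nothing on growth. CSNK1A1, the kinase casein kinase 1 alpha, fell by 1.17 (SD 1.19) with 4 of 6 guides down, but its sub-library A guides had a median of 0.04. SPDYE5 fell by 1.78 (SD 0.39, 4 of 4). LONP1 was called at -1.23 (SD 0.89, 5 of 6 guides down), but among its sub-library B guides a pair went only from 4 counts to 0 and from 1 to 0, and the third had 0 in both. LOC100132247 (-0.69, SD 0.62), PKD1 (-1.20, SD 1.29) and hsa-mir-6859-1 (-4.09, SD 1.89) fell as well. These 3 and SPDYE5 have near-identical copies, which makes them uncertain. DHX33, an RNA helicase of ribosome production, was called at -0.67 (SD 0.74), but 2 of its 4 kept guides went only from 1 count to 0. The lowest p-values for enrichment, at adjusted p = 0.502 by permutation, belonged to TUBGCP3, PLCD3, PPP4R1, MYL5 and ZFAND6, the last with 4 of 5 guides up (1.30, SD 0.90) and TUBGCP3 with 1 of 4 (-0.93, SD 4.18).

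PSMG4, which encodes a chaperone of proteasome assembly, was among the 9 called targets (log2 fold change -0.67, SD 1.40, adjusted p = 0.0458 by permutation, 3 of 5 guides down). A pair of its sub-library A guides went from 3975 to 466 counts (ratio of scaled counts 0.130, exact 95% interval 0.118 to 0.143) and from 3561 to 758 (0.236, interval 0.218 to 0.255). The other sub-library A guide went from 649 to 747 (1.28, interval 1.15 to 1.42), and a sub-library B guide from 1979 to 1798 (1.01, interval 0.945 to 1.07). The third guide counted as down went only from 1 count to 0. PSMG4 stayed called in 10 of 17 alternative settings. PSMG2, which encodes the assembly chaperone named in the title of the series, had 3 kept guides of 6 and was not called. A PSMG2 guide went from 1853 counts in DMSO-Day7 to 803 in AZD-Day7 (ratio 0.481, interval 0.442 to 0.523), another from 203 to 212 (1.16, interval 0.951 to 1.41), and the third, with 558 counts in DMSO-Day0, had 0 in both day 7 libraries. The remaining PSMG2 guides had at most 34 counts in any library. PSMG3 had a value of -1.09 (SD 1.06, 3 of 4 guides down, 1 of them only from 3 counts to 0), POMP one of -0.46 (SD 1.02, 3 of 4 down) and PSMG1 one of 0, with 2 of its 3 kept guides at 0 counts in both day 7 libraries and the third going from 1642 to 801 (ratio 0.541, interval 0.497 to 0.589), and none of these was called. The 9 proteasome assembly chaperones had a median of -0.17 (percentile 3.86), 1 was called over all targets, and PSMG3 and PSMG4 passed when adjusted over the list alone. MAP2K1 had a value of 0.32 (SD 0.70, 2 of 4 guides up) and MAP2K2 one of 0.16 (SD 0.59), with only 2 of its 4 kept guides above 5 counts at day 7.

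**Figure D3:**
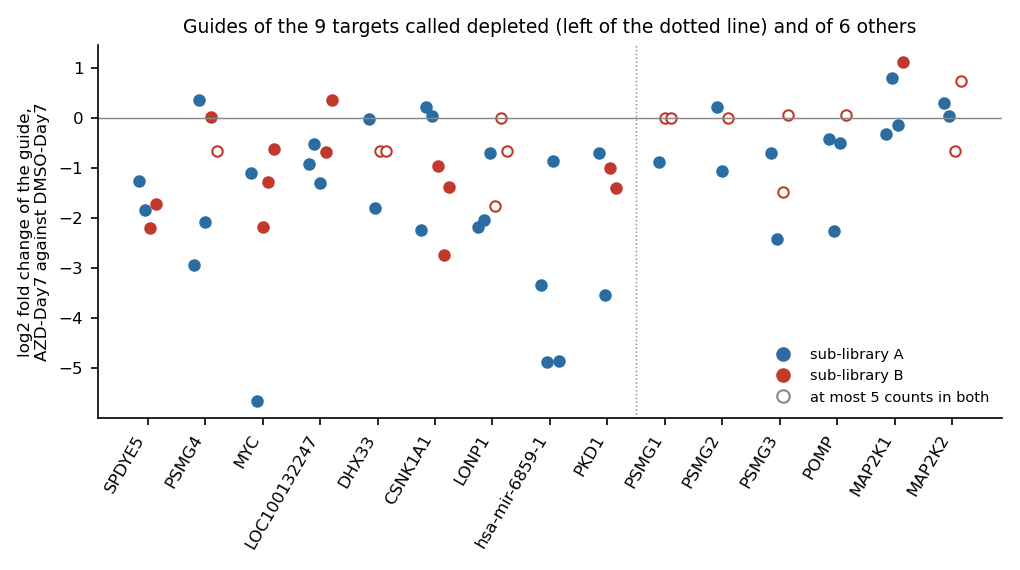
Log2 fold change of each kept guide in AZD-Day7 against DMSO-Day7 (vertical axis) for the 9 targets called depleted, left of the dotted line, and for the other proteasome assembly chaperones and the MEK genes (horizontal axis). Each point is a guide, blue for sub-library A and red for sub-library B, open where both day 7 counts were at most 5. All 4 SPDYE5 guides and all 5 MYC guides lie below 0, while PSMG4 has 2 guides below -2 and 2 above 0.

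With the pair filter, which drops guides absent from both day 7 libraries, 20 targets were called depleted and 0 enriched, of 14595 tested. At an unadjusted p under 0.05 these were 776 and 730, where 730 would arise by chance in each direction. The called targets included 6 of the 9 above, of which 7 could be tested, namely SPDYE5, PSMG4, MYC, LOC100132247, CSNK1A1 and PKD1. Of the other 14, POP5 (-1.24, SD 1.41), LSM11, a component of the U7 particle for histone mRNA (-1.21, SD 0.61), and CRCP, a subunit of RNA polymerase III (-1.71, SD 1.57), fell. So did UBE2M, a conjugating enzyme for NEDD8 (-1.38, SD 0.98), and HSPE1, the mitochondrial chaperonin partner (-1.36, SD 0.65, 5 of 5 guides down). MLST8, a subunit of the mTOR complexes (-0.97, SD 0.24), FAM96B of iron-sulfur protein assembly (-1.09, SD 0.55), VPS25 of the ESCRT machinery (-2.05, SD 1.40), ARFRP1 (-1.14), TINF2 (-0.95) and BRAT1 (-0.69) fell as well, as did SPDYE2 (-0.67) and hsa-mir-4419a (-5.49). PSMG4 had a value of -1.03 in this setting and PSMG2 was left with too few guides.

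In the gene lists of this comparison with all guides, medians lay below the random range for RNA polymerases and transcription factors (-0.21), ribosomal proteins (-0.20, 42 of 62 members below 0), DNA replication (-0.17), ubiquitin system and p97 (-0.14), aminoacyl-tRNA synthetases (-0.13), the PI3K-AKT-mTOR pathway (-0.13), the spliceosome (-0.12), mitosis and cohesin (-0.10) and translation factors (-0.07). No list with guides in both sub-libraries lay above it, and the median of microRNA targets (0.03, and -0.04 under non-targeting scaling) lay within the range of random lists from sub-library A (percentile 96.8). Adjusted over the list alone, 8 genes of the ubiquitin system passed, among them CUL1, NEDD8 and UBE2M. For DNA replication 6 passed, among them GINS3 (-1.13) and GINS4 (-1.53) of the replicative helicase, and for the other lists at most 3 passed in either direction. CCT4, CCT8 and TCP1 of TRiC, PSMA7, PSMD7 and PSMD8 of the proteasome, AARS, FARSA and YARS, and MLST8 were among them as depleted. AMOTL2 (0.86, 4 of 4 guides up), CDKN2A, TADA1 and EIF5A were those that passed as enriched. None of these except MYC, PSMG4 and hsa-mir-6859-1 passed over all targets.

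The lists within the random range included those closest to the drug target. Positive members of the ERK pathway had a median of 0.05 (percentile 92.7), negative regulators of it 0.02 (79.0), and reported modifiers of MEK or RAF inhibitor response 0.03 (86.9). Medians were -0.23 for TRiC (3.26), -0.12 for the vacuolar ATPase (3.44), -0.05 for autophagy (3.88), -0.04 for the mitochondrial ribosome (3.18), -0.04 for proteasome subunits (7.11), -0.04 for cell cycle kinases and G1/S regulators (8.38) and -0.01 for oxidative phosphorylation (15.9). They were 0 for apoptosis regulators, for lysosomal proteins and for the heat shock and unfolded protein responses, 0.01 for SWI/SNF, Mediator and SAGA (70.2), 0.01 for olfactory receptors (97.1) and 0.03 for growth-suppressing regulators (83.8). Kept guides with 0 counts in both day 7 libraries score 0, which draws medians over all guides towards 0. The random lists had a median of 0 as well. A median of 0 here therefore does not show a lack of change.

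With the pair filter most housekeeping medians lay lower, at -0.43 for TRiC, -0.36 for proteasome assembly chaperones (5 genes), -0.35 for the spliceosome, -0.32 for DNA replication, -0.22 for proteasome subunits, -0.13 for the mitochondrial ribosome and -0.10 for autophagy genes, all below the random range. Growth-suppressing regulators had a median of 0.15 (percentile 99.6), with 9 of 29 members below 0. AMOTL2, an angiomotin of the Hippo pathway, was highest at 1.32 (SD 0.69, 3 of 3 guides up), and TAOK1 stood at 0.67, TSC1 at 0.46 and the cell cycle inhibitor CDKN2A at 0.46 (SD 0.10, 5 of 5 up). The growth-suppressing list was within the random range with all guides and with sub-library A alone (0.10, percentile 87.3). With 1 library per group, none of these differences was checked against a second culture, and pseudocounts of 5 or 10 left 1 called target, SPDYE5.

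**Figure D4:**
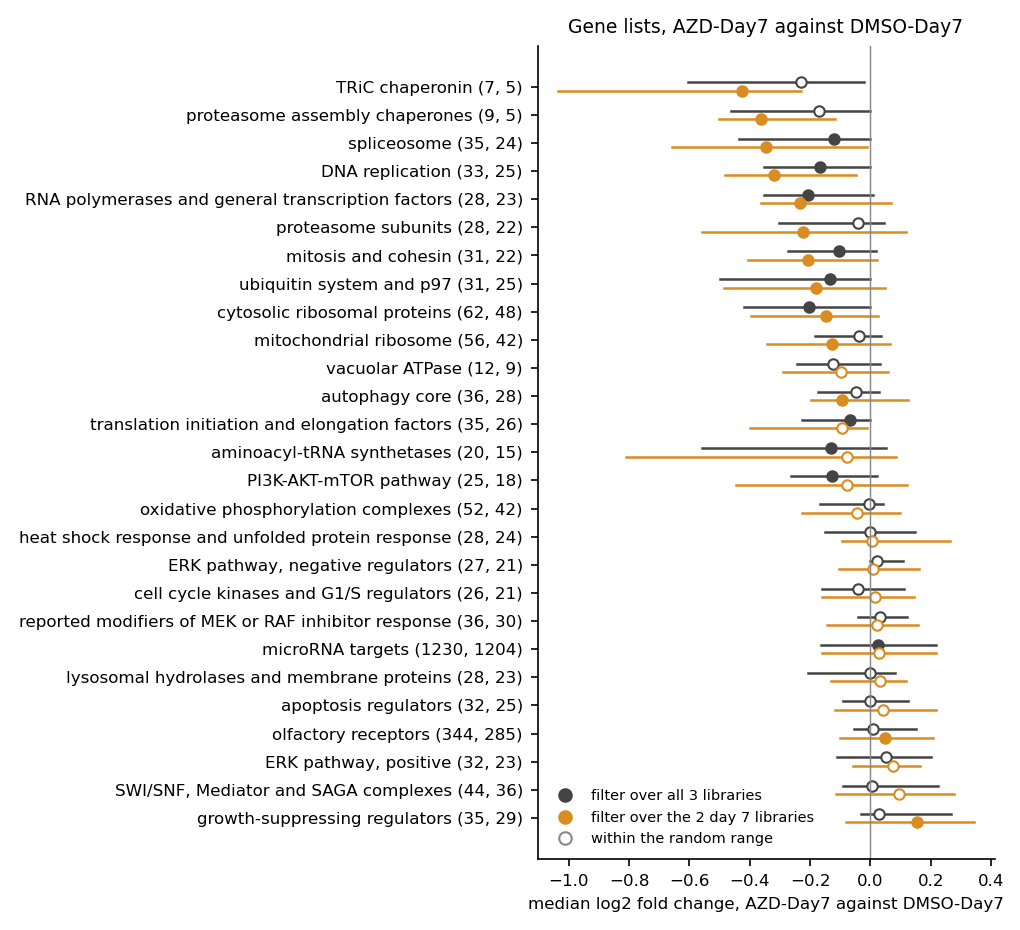
Median log2 fold change of AZD-Day7 against DMSO-Day7 (horizontal axis) of each gene list (vertical axis, members measured under each filter in parentheses), with the filter over all 3 libraries (grey) and over the 2 day 7 libraries (orange). Lines span the interquartile range of members, and filled points lie outside the central 95% of random lists. TRiC lay at -0.23 and -0.43, the spliceosome at -0.12 and -0.35, and growth-suppressing regulators at 0.03 and 0.15.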

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

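In this part, the tests of separate loss and of a shared bottleneck were chosen only after the result had been seen. Both results below concern the loss of guides by sub-library or kind, which no comparison between conditions measured. Non-targeting guides, which have no target in the genome, had at most 5 counts in both day 7 libraries for 67 of 820 guides with at least 100 counts in DMSO-Day0 (8.17%, exact 95% interval 6.39 to 10.3%). That was above the 0.0433% of sub-library A gene guides, although all non-targeting guides stood under A names. If each non-targeting guide was present in both sub-libraries, 7.03% would have been lost. Sub-library B guides were lost at 53.0%.

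The loss in sub-library B was weighed against technical causes, and against death of knocked-out cells. No other biological explanation was tested, since the design names none that would act on a sub-library. Separate loss in each day 7 culture or library is ruled out as the whole cause, because the share lost in both was 1.83 times the product of the single shares. Death of knocked-out cells is ruled out likewise, because 51.4% of sub-library B guides against olfactory receptors were lost. A bottleneck of sub-library B cells shared by both day 7 cultures could have caused the pattern, as the share lost was 3.73 times as high in the lowest step of DMSO-Day0 counts as in the highest, and the day 7 libraries correlated more closely with each other than with DMSO-Day0. That explanation was formed on these same values, and records of cell numbers at the division of the pool would be needed to test it.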

How the results depend on the processing

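The pair filter and the restriction of the growth ratio to sub-library A were chosen only after results had been seen. No paired analysis was possible because each group had 1 library. The alternative with guides of a single perfect genomic site was not run, since no guide sequences or genome were used here. Without replicates, depth limits single guides through counting error, and loss of sub-library B guides limits values against DMSO-Day0 that include such guides. Of the other values, 5993 of named genes kept their side of the threshold, 25 passed only in an alternative and 96 no longer passed. A change of sign was checked only in targets called in the main setting. Uncalled targets that stayed uncalled count among the 5993, whatever their sign. Of list medians 653 stayed within their interval and 218 moved outside it. Of counts, spreads and growth ratios 138 stayed and 43 moved. For everything below the cause was not tested, except where fewer guides or a stricter threshold is itself the change.

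In DMSO-Day7 against DMSO-Day0, where 0 targets were called, a pseudocount of 10 gave 1 enriched, and depleted targets numbered 3 by the sum method, 4 with the most extreme guide left out, 10 with sub-library A and 3 with sub-library B. Counts of lists above the random range include microRNA targets, which have no sub-library B guides and so were not comparable with random lists of all guides. Against 10 lists below and 2 above, sub-library B gave 0 and 1, means over guides 2 and 1, and no filter 1 above. In AZD-Day7 against DMSO-Day0, against 9 depleted and 0 enriched, a pseudocount of 10 gave 2 enriched, plain log2 ranking 0 depleted, the sum method 5 depleted and 1 enriched, sub-library A 19 depleted, sub-library B 5, and a threshold of 0.05 left 5. Lists below the range numbered 0 with sub-library B and 5 with means over guides, and those above 1 with no filter and 1 with means.

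In AZD-Day7 against DMSO-Day7, against 9 depleted, pseudocounts of 5 and 10 each gave 1, no filter 1, a filter on DMSO-Day0 14, the sum method 0, leaving out the most extreme guide 14, sub-library B 2, a threshold of 0.05 left 4, the pair filter gave 20 and the growth correction, with a slope of 1.55, gave 0. Plain log2 ranking called 8 and shared 2 of the 9, without MYC and PSMG4, and sub-library A called 9 and shared 3 of the 5 testable. Lists below the range numbered 5 with no filter and 1 with sub-library B. Lists above it numbered 0 with non-targeting scaling, 2 with pseudocounts of 5 and of 10, 0 with no filter, 2 with a filter on DMSO-Day0, 2 with means over guides and 2 with the pair filter. With a pseudocount of 5 the SD of non-targeting guides was 2.30 in DMSO-Day7 and 2.32 in AZD-Day7 against DMSO-Day0. The growth ratio was 2.31 with sub-library A under the main scaling, and was not computed there under other scalings.

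Signs were checked only in targets called, and lists outside the random range, in the main setting, and among these they changed as follows. Lists within the range changed sign too, such as growth-suppressing regulators with sub-library A in both comparisons against DMSO-Day0. The median of olfactory receptors was 0.13 with total counts, 0.10 with non-targeting scaling and 0.20 with sub-library A in DMSO-Day7 against DMSO-Day0, and 0.15, 0.062 and 0.14 in AZD-Day7. With sub-library A, the mitochondrial ribosome stood at 0.029 in DMSO-Day7 against DMSO-Day0, ENPP7 at 0.34 in AZD-Day7 against DMSO-Day0, and CSNK1A1 at 0.042 between the day 7 libraries. There, microRNA targets stood at -0.039 with non-targeting scaling, and after the growth correction DHX33 stood at 1.98, LONP1 at 1.29 and PSMG4 at 0.23. These 3 each have sub-library B guides lost at day 7, whose values the correction raises by construction, so the change of sign says nothing on growth.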

Other observations

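In this part, the tests of a longer outgrowth and of swapped labels were chosen only after the result had been seen. The following single genes of sub-library A were picked after their values had been seen. GINS4, a subunit of the replicative helicase, had a log2 fold change of -0.12 in DMSO-Day7 (SD 0.79 over 3 guides) and -2.69 in AZD-Day7 (SD 1.49), both against DMSO-Day0. TCP1 of TRiC stood at -2.04 and -4.20, the spliceosomal helicase SNRNP200 at -1.19 and -3.20, the alanyl-tRNA synthetase AARS at -1.20 and -2.54, and the translation factor EIF3D at -1.23 and -2.50. The kinetochore gene SPC24 (-2.30 and -3.18) and the proteasome subunit gene PSMB7 (-1.94 and -2.65) were low in both cultures. MLST8 stood at 0.28 without drug (SD 0.25) and at -0.76 with drug (SD 0.042, 3 of 3 guides down). None of these was called with sub-library A guides.

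Essential gene lists lay lower in AZD-Day7 than in DMSO-Day7, and the drug itself, which the design names, stays open as a cause. A scaling offset between the day 7 libraries is ruled out as the whole cause, because in sub-library A 491 essential guides lay 0.29 below 902 olfactory receptor guides (difference -0.29, bootstrap 95% interval -0.37 to -0.21). A longer or faster outgrowth of the AZD-Day7 culture cannot be told apart from a drug effect. The pooled ratio in sub-library A, 2.31, holds for the main scaling only, and so cannot measure outgrowth. The ratios of single lists had intervals too wide to compare (-27.4 to 12.4 for the spliceosome). Swapped labels of the day 7 libraries cannot be told apart either, as negative regulators of the ERK pathway lay within the random range (percentile 79.0). Counts of cell doublings in each culture and a second pair of cultures would be needed to decide.

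Guides that act at several genomic sites were expected to lower microRNA targets named as numbered copies, but 161 of these lay 0.018 above 1069 others in AZD-Day7 against DMSO-Day0 (random range -0.084 to 0.076), so that as a class they were not lower. The class was formed from names, and the number of matching sites per guide was not known. The result therefore says nothing on guides that do cut at several sites, or on the called targets from multicopy families. If sub-library B cells at day 7 descended from few founders already past selection, their essential guides would be less depleted between the day 7 libraries. That cannot be told, as the median of 158 essential sub-library B guides differed by 0.022 from that of 476 sub-library A guides (interval -0.078 to 0.14). The comparison does not test whether founders were few. Amplified segments cannot be told apart from none. The rank correlation of 8203 neighbouring gene pairs was 0.020 in DMSO-Day7 against DMSO-Day0, just inside the range of 1000 shuffled orders (-0.022 to 0.022). It was 0.058 in AZD-Day7 against DMSO-Day0, above the shuffled range. By the range fixed before the test, the DMSO-Day7 value alone would have spoken against such segments, and the milder reading was adopted after both values were seen.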
